A study of Mus musculus with 8 samples.

How the data were processed

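RNA was measured in cultured bEnd.3 cells, an immortalised endothelial cell line from mouse brain. The Mut group (3 libraries) had received a lentivirus carrying MAP3K3 with the change I441M, and the Ctrl group (5 libraries) a lentivirus carrying EGFP. The design text numbers the control samples as Ctrl 1 to 4, while the labels list 5, and all 5 were used. RNA came from a low-input extraction kit (RNeasy Micro) and the libraries from a stranded total-RNA kit (SMARTer, Takara). The submitters' processing notes name HISAT, HISAT2, DESeq2 and the mouse genome build GRCm38, without versions. The counting tool and the annotation release are not given in the sources used here.

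The single deposited table holds the authors' comparison of both groups for 3574 genes. The coverage signal in its per-library columns is the deposited normalized read count: whole reads divided by 1 size factor per library. Every value was checked to be a whole multiple of 1 step per library within 0.01 read, so the reads themselves were recovered. The authors also deposited a log2 fold change with its standard error, and a p-value with its adjusted p-value, for each gene. Every listed gene has an adjusted p below 0.01 and an absolute log2 fold change above 1.5 in the authors' table. From the ratio of p to adjusted p, the authors' adjustment covered 28634 genes, of which 8932 (31.2%) had a p at or below the largest one listed. The genes left out of the table were not analysed here, and the total depth of the libraries is unknown. The Ctrl columns carry the numbers of the Ctrl labels. The Mut libraries are numbered 1 to 3 by the order of their columns, as the table calls them by another name.

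Each library had between 4244981 and 12084413 reads in the listed genes. The value of 1 read was 0.509 to 0.941 normalized counts in the Ctrl libraries, and 2.30, 0.881 and 1.68 in Mut 1, 2 and 3. Where all 3 Mut libraries were at 0, a floor of 3 reads over the Mut group (1.39 normalized counts) was used, and the fold is given as a lower bound. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where few molecules entered a library, 0 reads can arise by sampling, and these folds are not bounds against that. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between libraries.

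The groups were compared with limma 3.58.1 in R 4.3.3 (trend and robust options) on log2 of the normalized count plus 1. Genes needed a mean of at least 1 over all 8 libraries, and the test was two-sided with Benjamini-Hochberg adjustment over the 3574 listed genes and a threshold of 0.05. This was the test fixed for normalized values, in place of the one planned for raw counts. Values are means ± SD of normalized counts, with n = 5 for Ctrl and n = 3 for Mut. Folds are ratios of group means, and log2 fold changes are limma estimates ± SE, Mut minus Ctrl. Gene positions came from a GRCm38 annotation that matched 3572 of the 3574 gene identifiers. Of these, 3568 were protein-coding and 4 of other kinds, so the table tells almost nothing about non-coding RNAs. Genes whose span overlaps another protein-coding gene are named as such.

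The groups, the test, 36 gene lists and the rule for naming genes were chosen before the data were examined. The rule took a set of core genes of the pathway, the 12 largest increases and 12 largest decreases without overlap between groups, up to 4 members of each list by adjusted p, and the most abundant gene of each group. Lists with at least 5 listed members (25 of 36) were tested with camera in limma, with a preset correlation of 0.01 between genes. Camera compares a list with the other listed genes, all of which the authors had chosen on these libraries, so no list was tested against the genome. The same lists were also tested with the correlation estimated and with fry. Directions of list members were compared with those of all listed genes by Fisher's exact test (two-sided, SciPy 1.17.1), adjusted over the 25 lists.

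Alternatives covered the added count (0.1), no filter or a mean of at least 5, DESeq2 1.42.0 and limma-voom on the recovered reads, median-of-ratios factors, reads thinned to the smallest library, and each library left out in turn. A stricter threshold (0.01) and a minimum log2 fold change of 1 were also applied. Added after the table was seen were edgeR 4.0.16 on the recovered reads, factors from TMM or from the total of the listed reads, 2 subsets of the Ctrl libraries, a mean of at least 200 over all 8 libraries, and lists without members nested in another member. The subsets follow the reads. Between pairs of Ctrl libraries the chi-square per degree of freedom was 4.93 for Ctrl 3 and 4 and 8.02 to 12.4 among Ctrl 1, 2 and 5, but 15.7 to 35.2 between these 2 sets. The labels do not say what sets them apart, and the tests with n = 5 treat the 5 libraries as independent. The planned block by replicate number was left out, because the numbers do not pair Mut with Ctrl libraries. The tests were also tried on simulated data. Analyses outside limma, edgeR and DESeq2 used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.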

Results

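Transcripts of bEnd.3 mouse brain endothelial cells were profiled after lentiviral delivery of MAP3K3 I441M (Mut, n = 3) or of EGFP (Ctrl, n = 5). MAP3K3 encodes MEKK3, a kinase at the head of a MAP kinase cascade. The Ctrl libraries had 8107918, 5973152, 4244981, 5431982 and 5222434 reads in the 3574 listed genes. The Mut libraries had 5264122, 12084413 and 6415709. The listed genes summed to 4.10 ± 0.104 M normalized counts in Ctrl and 11.2 ± 0.811 M in Mut, 2.73-fold more. Between 21 and 54 listed genes had no read in a Ctrl library, against 1272, 616 and 1111 in Mut 1, 2 and 3. Plec, which encodes the cytolinker plectin, had the highest mean in both groups, 72902 ± 5440.3 in Ctrl and 251171 ± 68723 in Mut. Its span overlaps Parp10.

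The single comparison, Mut against Ctrl, asks what a virus with MAP3K3 I441M changes in endothelial cells against a virus with EGFP. The series title ties the variant to cerebral cavernous malformations. No library received wild-type MAP3K3, so effects of the I441M change are not separated from those of added MAP3K3. Map3k3 is not in the table, so no rise past the authors' limits is listed, and delivery of MAP3K3 to the Mut cells is unverified. The species of the construct is not stated. Klf2 and Klf4, the flow-responsive transcription factors downstream of MEKK3, were 3.47-fold and 3.63-fold higher in Mut. Most listed genes of MAP kinase feedback, glycolysis and adhesion were higher too, among them Phlda1 (46.8-fold), Ndrg1 (40.8-fold) and Itga5 (7.89-fold). All listed members of 3 cell division lists were lower, with Mki67, the proliferation marker, 14.0-fold and the replication helicase gene Mcm4 7.64-fold below Ctrl (n = 3 and 5 throughout). By limma, 3458 of the 3574 listed genes passed the threshold, 1265 higher and 2193 lower, and the other 116 were all listed as higher. With size factors made from the listed genes, 775 (median of ratios), 1125 (TMM) or 817 (total) were higher and 2193 lower. Log2 fold changes then shift by -1.49, -0.80 or -1.45, but less for genes with few Mut reads, through the added count of 1. Such factors assume that genes chosen as changed are unchanged on balance, so the lost and kept calls do not decide between scalings. Mut and Ctrl values did not overlap in 3371 genes (94.3%, where chance gives 3.57%). Because the authors had selected these genes on the same libraries, the counts are not independent evidence.

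**Figure D1:**
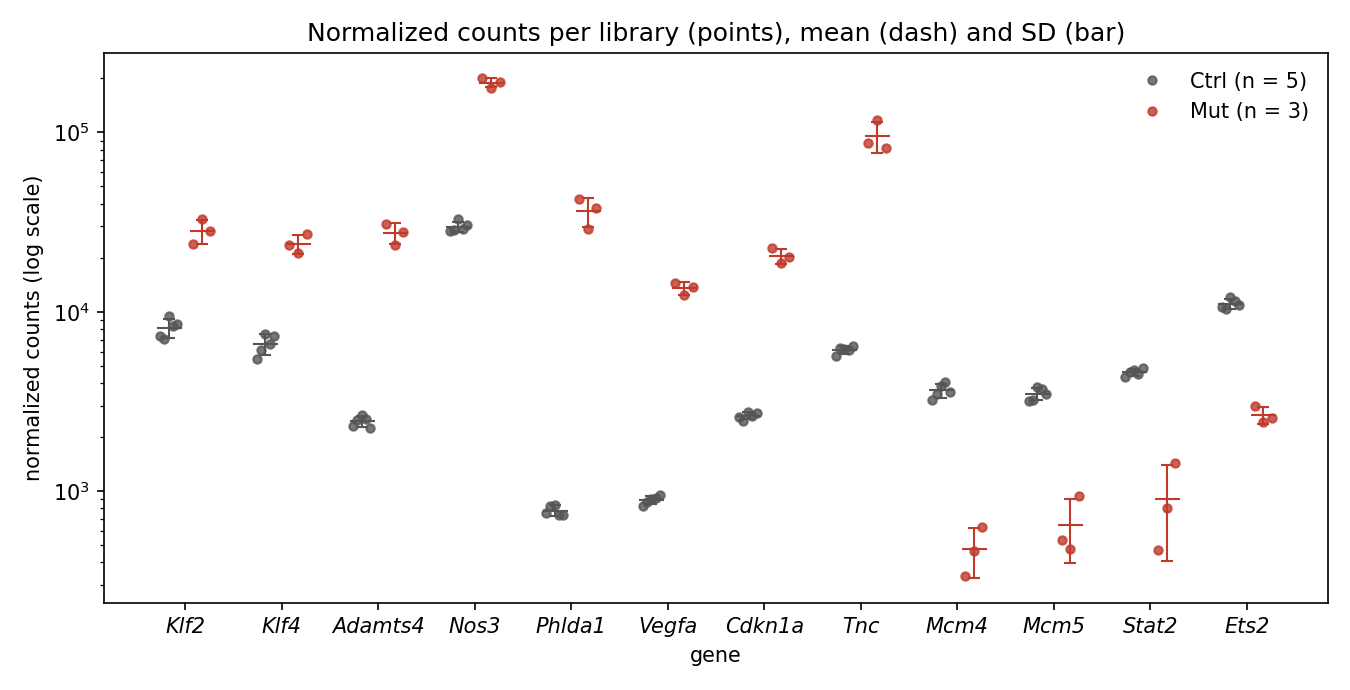
Normalized read counts (log axis) of 12 genes in the 5 Ctrl and 3 Mut libraries; points are libraries, dashes group means and bars SD. Klf2, Klf4, Adamts4, Nos3, Phlda1, Vegfa, Cdkn1a and Tnc lay higher in all 3 Mut libraries than in any Ctrl library, and Mcm4, Mcm5, Stat2 and Ets2 lower.

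The MEKK3-KLF list holds genes of the cascade and its reported targets. Of its 32 genes, 11 were listed: 7 rose and 4 fell, and the same 11 passed adjusted over the list alone. Here and in the lists below, such passes were likely from the start, since the authors chose all listed genes on these libraries. They are no independent evidence. Klf2 (ENSMUSG00000055148.7, chromosome 8, 72319033 to 72321656) rose from 8142 ± 980.0 to 28283 ± 4392 (log2 1.79 ± 0.13, adjusted p = 2.54e-06). Klf4 (ENSMUSG00000003032.8, chromosome 4, 55527143 to 55532466) rose from 6622 ± 869 to 24021 ± 2948 (log2 1.86 ± 0.13, adjusted p = 1.91e-06). Adamts4 (ENSMUSG00000006403.13, chromosome 1, 171250421 to 171260637), which encodes a versican-cleaving protease, rose 11.2-fold from 2453 ± 162 to 27456 ± 3612 (adjusted p = 3.26e-08). Nos3 (ENSMUSG00000028978.12, chromosome 5, 24364810 to 24384474), the endothelial nitric oxide synthase, rose 6.35-fold from 29873 ± 1846 to 189692 ± 11534 (adjusted p = 1.33e-08). The spans of Adamts4 and Nos3 overlap other protein-coding genes. Ptgs2 (ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, rose 5.00-fold from 1147 ± 103 to 5733 ± 1042 (adjusted p = 1.06e-06). Procr, the endothelial protein C receptor, rose 12.9-fold and Klf6 4.68-fold. Aqp1, a water channel gene named after its value was seen, fell 9.78-fold, or 24.2-fold without Mut 2. The list as a whole did not pass (camera adjusted p = 0.0560, and adjusted p = 0.271 with an estimated correlation). When size factors were made from the listed genes alone, by median of ratios or by total, the log2 fold change of Klf2 was 0.30 or 0.35 and no longer passed, and that of Klf4 was 0.37 or 0.42 and passed. Map3k3, Map2k5, Mapk7, Krit1, Ccm2, Pdcd10, Heg1, Adamts5 and Thbd are not in the table and were not analysed here.

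Among immediate early and MAP kinase feedback genes, 15 of 34 were listed, 13 rose and 2 fell. Phlda1, a gene induced by growth factor signalling, rose from 779 ± 52.2 to 36448 ± 6894. Spry2, an inhibitor of receptor tyrosine kinase signalling, rose from 221 ± 19.9 to 9359 ± 1261. The MAP kinase phosphatase genes Dusp4 and Dusp5 rose 15.2-fold and 10.6-fold. Dusp6, a phosphatase gene named after its value was seen, fell from 9175 ± 485 to 2673 ± 757. The list moved up relative to the other listed genes (camera adjusted p = 6.93e-05, but adjusted p = 0.0740 with an estimated correlation).

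All listed members of 3 lists of cell division fell. For cell cycle and mitosis these were 17 of 32 genes and for DNA replication 19 of 37. For replication-dependent histones they were 11 genes from 25 symbols, some of which are 2 names of 1 gene, such as Hist1h1d and H1f3. The same numbers passed adjusted over the list alone. Mki67, named after its value was seen, fell from 15190.2 ± 655 to 1086 ± 793, and the mitotic kinase gene Plk1 from 615 ± 86.9 to 9.71 ± 7.22. Bub1, of the spindle checkpoint, fell from 674 ± 49.1 to 2.00 ± 1.77. The fold decrease of Plk1 went from 63.4 to 99.3 without Mut 2, and that of Bub1 from 337 to 509.9 without Mut 3. The helicase genes Mcm4 and Mcm5 fell 7.64-fold (adjusted p = 1.74e-06) and 5.37-fold (adjusted p = 8.31e-06), and Ccne1, the gene for cyclin E1, fell 158-fold, or 105-fold without Mut 1. The linker histone gene Hist1h1d fell from 4123 ± 543 to 515 ± 22.1. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 7.75-fold from 2638 ± 121 to 20434 ± 2020.3 (adjusted p = 3.27e-08). It was 1 of 3 listed genes of the 26 p53 and senescence genes, and the others fell, Zmat3 from 2210.3 ± 151 to 527 ± 283 and Gdf15 at least 14.7-fold, with no Mut read. Camera gave adjusted p = 0.0126, 0.0123 and 0.0302 for the cell cycle, replication and histone lists. These became adjusted p = 0.196, 0.285 and 0.396 with an estimated correlation. Against the direction of all listed genes, Fisher's exact test, which counts genes that move together as independent, gave adjusted p = 0.00138, 0.00112 and 0.0323.

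Of 32 hypoxia and glycolysis genes, 11 were listed, and all 11 rose and passed, also adjusted over the list alone. The authors' selection of listed genes on these libraries left little room for another outcome of that test. Slc2a1, the glucose transporter of brain endothelium, rose from 3023 ± 237 to 15824 ± 839, and Hk1, the first enzyme of glycolysis, from 6461 ± 325 to 23056 ± 2668. The hypoxia-responsive gene Ndrg1 rose 40.8-fold and Vegfa, the vascular growth factor, 15.1-fold. The list passed camera (adjusted p = 6.93e-05, but adjusted p = 0.254 with an estimated correlation), and 8 members passed with the median-of-ratios or total factors.

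Of 34 junction and adhesion genes, 15 were listed, and 13 rose while 2 fell. The integrin genes Itga5 and Itga6 rose 7.89-fold and 3.85-fold, and Tln1, which links integrins to actin, rose 5.31-fold, with a span overlapping Creb3. The list passed camera (adjusted p = 6.93e-05), but gave adjusted p = 0.0740 with an estimated correlation, and 9 and 11 members passed as higher with the median-of-ratios and total factors.

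Matrix genes went both ways. Of 41 basement membrane and matrix genes, 12 were listed, 5 rising and 7 falling (camera adjusted p = 0.894). Tnc, a matrix glycoprotein gene, rose from 6151 ± 310.4 to 95324 ± 18711, and Lama4, a laminin of endothelial basement membrane, rose 10.3-fold. Vcan, which encodes the ADAMTS4 substrate versican, rose 15.6-fold, while Bgn fell at least 18.3-fold, with no Mut read. Of 34 matrix proteases and inhibitors, 15 were listed, 9 rose, 5 fell and 1 did not pass, Mmp13, named for that reason (log2 1.89 ± 1.40). Single Mut libraries decided that value, which was 3.91 and passed without Mut 1, and was 0.21 without Mut 2. With the median-of-ratios and total factors, 5 and 6 members of the list passed as higher, against 5 lower. Plaur, the urokinase receptor, rose 44.2-fold, and Timp1, which lies within Syn1, rose 84.5-fold. Of 24 coagulation genes, 15 were listed, 10 rose and 5 fell. Plat, tissue plasminogen activator, rose 10.2-fold, Anxa2, a plasminogen receptor gene, 6.97-fold, and Procr from 2672 ± 251 to 34559.7 ± 4552. The protease and coagulation lists passed camera (adjusted p = 0.0409 and 0.0123), but gave adjusted p = 0.250 and adjusted p = 0.200 with an estimated correlation, and 8 coagulation genes passed as higher with those factors.

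Endothelial genes did not move as a block. Of 34 pan-endothelial genes, 7 were listed, 3 rose and 4 fell (camera adjusted p = 0.894). The transcription factor genes Fli1 and Ets2 fell, from 24016 ± 3116 to 5275 ± 2270.3 and from 11095 ± 686 to 2653 ± 293. Tek, the angiopoietin receptor, rose 3.02-fold from 6627 ± 303, and Vwf, von Willebrand factor, 5.53-fold from 432 ± 63.1. With the median-of-ratios or total factors above, Tek no longer passed (log2 0.10 or 0.14), and 1 pan-endothelial gene passed as higher. Of 22 arterial and Notch genes, 2 rose and 3 fell (camera adjusted p = 0.894). The Notch ligand genes Jag1 and Dll4 rose 6.57-fold and 5.39-fold, and Nrp1, a VEGF co-receptor, fell 5.94-fold. Of 28 tip cell and angiogenesis genes, 8 rose and 4 fell, with Igfbp3 up 8.41-fold to 228024 ± 14821 and placental growth factor, Pgf, 12.7-fold. That list had a camera adjusted p = 0.0409 and adjusted p = 0.196 with an estimated correlation, and 6 members passed as higher with those factors. Of 35 blood-brain barrier genes, 4 rose and 6 fell (camera adjusted p = 0.894). The efflux pump gene Abcb1a rose 133-fold from 25.3 ± 4.46 (86.8-fold without Mut 2), while Slc7a5, whose span overlaps Gm20388, fell 4.91-fold. Cdh5, Pecam1, Cldn5 and Angpt2 are not in the table and were not analysed here.

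Inflammatory genes also split. All 7 listed genes of the 35 type I interferon response symbols, of which Ddx58 and Rigi name 1 gene, fell (camera adjusted p = 0.125). Stat2, which carries the interferon signal, fell from 4605 ± 202 to 904 ± 494, the viral RNA sensor gene Ifih1 3.49-fold and Oas2 5.08-fold. Of 32 NF-kB targets and chemokines, 15 were listed, 5 rose and 10 fell (camera adjusted p = 0.932). Tnfaip3, a feedback inhibitor of NF-kB, rose 5.48-fold with Ptgs2, while the chemokine gene Ccl20 fell at least 9.04-fold, with no Mut read. Of 15 MHC class I and antigen presentation genes, 4 were listed. H2-D1, a class I heavy chain gene with close paralogs, rose 5.20-fold, while the peptide transporter gene Tap2 and the immunoproteasome gene Psmb8 fell 12.2-fold and 16.9-fold, or 24.3-fold and 41.0-fold without Mut 3. Psmb9, which overlaps Tap1, had no Mut read and fell at least 126-fold by read counting alone, from a Ctrl mean of 175. Of 30 TGF-beta and BMP genes, 3 rose and 5 fell (camera adjusted p = 0.932), with Bmp2, a BMP ligand gene, up 248-fold to 18214 ± 1796 and the receptor gene Tgfbr2 down 2.98-fold. With the median-of-ratios or total factors, 1 member of that list passed as higher.

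The 12 largest increases started from Ctrl means between 0.575 (Krtap4-16) and 270.4 (Inhba). Nppb, a natriuretic peptide gene, rose from 2.71 ± 3.89 to 4359.7 ± 2120.2, and Sox9, a developmental transcription factor gene, from 5.47 ± 4.66 to 4676 ± 1094. Inhba, the activin A subunit, rose 474-fold from 270.4 ± 101 to 128028 ± 14519 (adjusted p = 3.27e-08). The keratin gene Krt16 rose from 4.96 ± 5.61 to 6285 ± 1171, Sprr1a, a gene of the cornified envelope, from 38.5 to 33306 ± 7580.2, and the keratin gene Krt6a from 1.61 ± 3.06 to 1176 ± 889. The others were Krtap4-16, Stfa2, Stfa2l1, Xirp2, Ly6d and Tmprss11b, with Mut means of 1419.8, 32195, 1569, 20642, 1482 and 15781. Stfa2 and Stfa2l1 are paralogs. Without Ctrl 2 the fold increase went from 1611 to 3424 for Nppb, from 1268 to 2199.8 for Krt16, from 730.2 to 4616 for Krt6a and from 2471 to 3872 for Krtap4-16, or 4038 without Ctrl 4. Without Mut 1 it was 418 for Krt6a and, from 1035, 649 for Stfa2l1, which was at 1564 without Ctrl 1. Of 19 astrocyte and neuron markers, 6 were listed, 5 rose and 1 fell. The neurofilament genes Nefl and Nefm are 1 signal, since Nefl lies within Nefm, shares exon bases with it and had near-equal values in each library. That signal rose 158-fold to 170339 ± 30696 (Nefm), and Stmn2 rose 14.8-fold. That list passed camera (adjusted p = 0.00699, and 0.0226 without Nefl, but adjusted p = 0.196 with an estimated correlation). Of 15 epithelial markers, 7 were listed, 3 rose, 3 fell and 1 did not pass, Krt8, named for that reason (log2 2.47 ± 1.25; camera adjusted p = 0.894). Without Mut 1 Krt8 passed at 4.25, and without Mut 3 it was 0.83. With the median-of-ratios, total or TMM factors, 2 epithelial markers passed as higher. Krt19 rose 245-fold from 4.82 ± 1.95, while Cldn7 and Cldn4 fell at least 5.64-fold and 5.59-fold, with no Mut read.

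The 12 largest decreases, ranked by the fitted log2 fold change, held 5 genes with at most 2 reads over the 3 Mut libraries. Hist1h2af (Ctrl 441 ± 118) and Shcbp1 (Ctrl 489 ± 43.4) had 1 read each, Pmf1 (Ctrl 383 ± 42.6) and Troap (Ctrl 416 ± 62.6) 2 each, and Necab3 (Ctrl 203 ± 31.8), which overlaps Actl10, had 0. By read counting alone, Necab3 was at least 147-fold lower. The mitotic kinase genes Ttk (Ctrl 709.6 ± 44.0) and Nek2 (Ctrl 849 ± 91.7) had 13 and 10 reads, Bub1 5, and Cdca7 (Ctrl 607 ± 52.5), a cell division cycle gene, 4. Tnfrsf11a (Ctrl 656 ± 24.5), the receptor RANK, had 7. Kcnh3 (Ctrl 530.2 ± 72.4), which overlaps Mcrs1, and Fbxo31 (Ctrl 515 ± 17.5), which overlaps Gm20388, had 6 and 14. All Mut reads of Ttk, Kcnh3, Fbxo31, Hist1h2af and Pmf1 lay in Mut 2, so no fold is given for these.

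**Figure D2:**
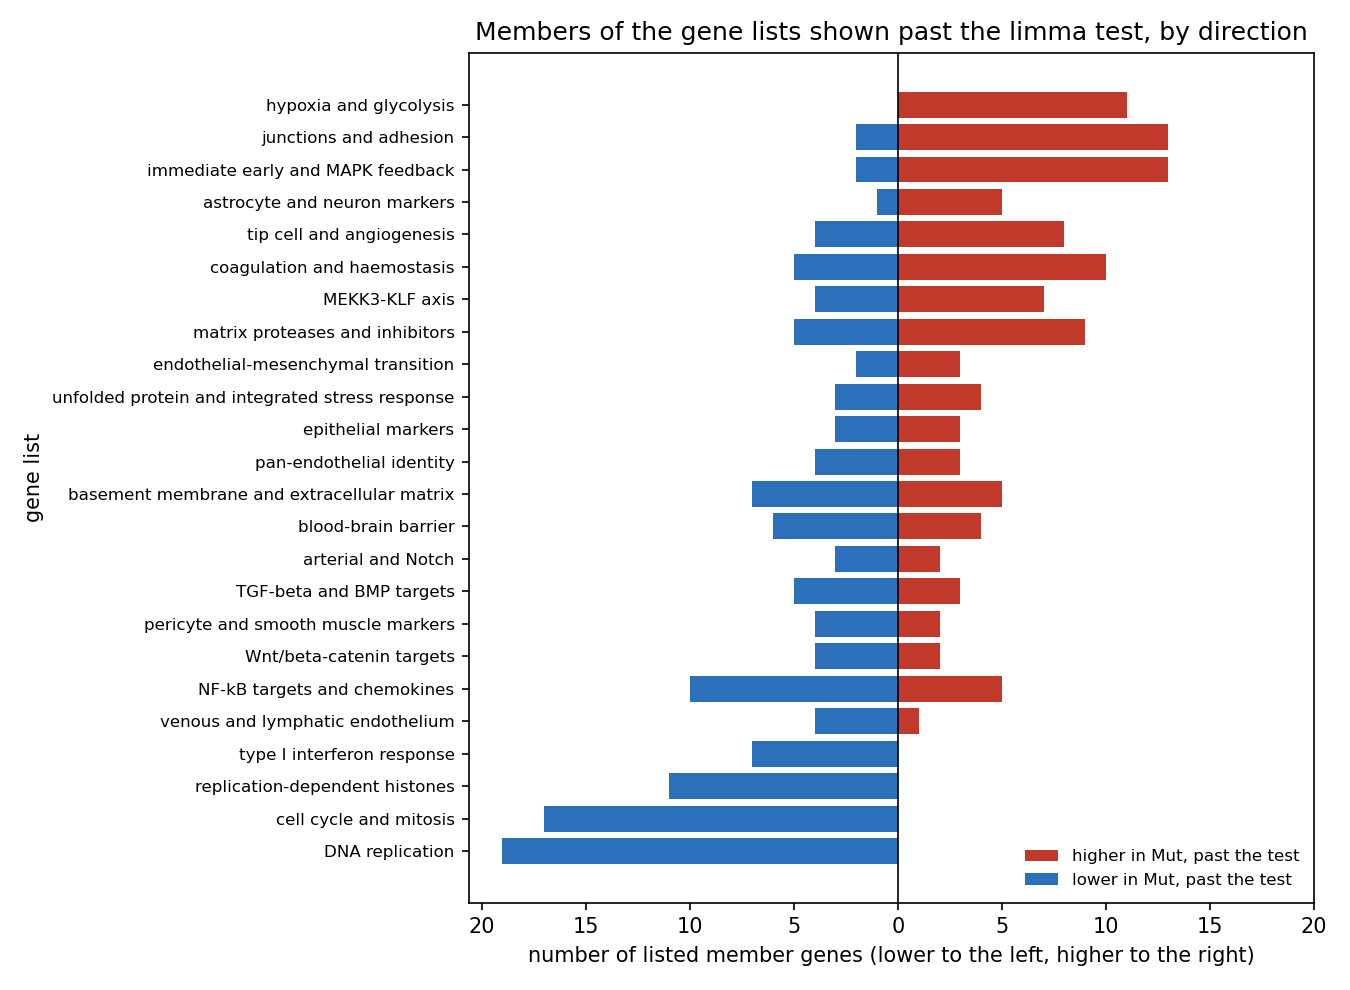
Number of listed members past the limma test in all but 1 of the 25 tested gene lists, higher (to the right) or lower (to the left) in Mut than in Ctrl. Glycolysis has 11 higher and 0 lower, and cell cycle 0 higher and 17 lower.

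Of the 25 lists tested, 11 passed camera, 8 up and 3 down, with the same number of members past the test adjusted over the list alone in every list. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.0740), 6 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way, called 22. The tip cell, protease and coagulation lists did not pass in every alternative at the preset correlation (largest adjusted p = 0.0821, 0.268 and 0.264). The Mut libraries scattered more than the Ctrl libraries at equal expression. Among genes with a group mean of 1000 to 3000, the median coefficient of variation was 7.44% in Ctrl and 42.2% in Mut. At 10000 to 30000 it was 7.47% and 14.9%. Each group was binned by its own mean, so the gene sets differ (520 genes in Ctrl and 400 in Mut at 1000 to 3000). Among listed genes with no Mut read, 532 in all, the median Ctrl level was 10.3. Of the 2193 genes listed as lower, 1373 had a Ctrl mean below 261, the level at which 3 units of the Mut scatter (variance per mean) fall in the 3 Mut libraries together. Gdf15, Bgn, Ccl20, Psmb9, Cldn4, Cldn7 and Necab3 were among these, and Mki67, Mcm4, Stat2 and Ets2 were not.

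**Figure D3:**
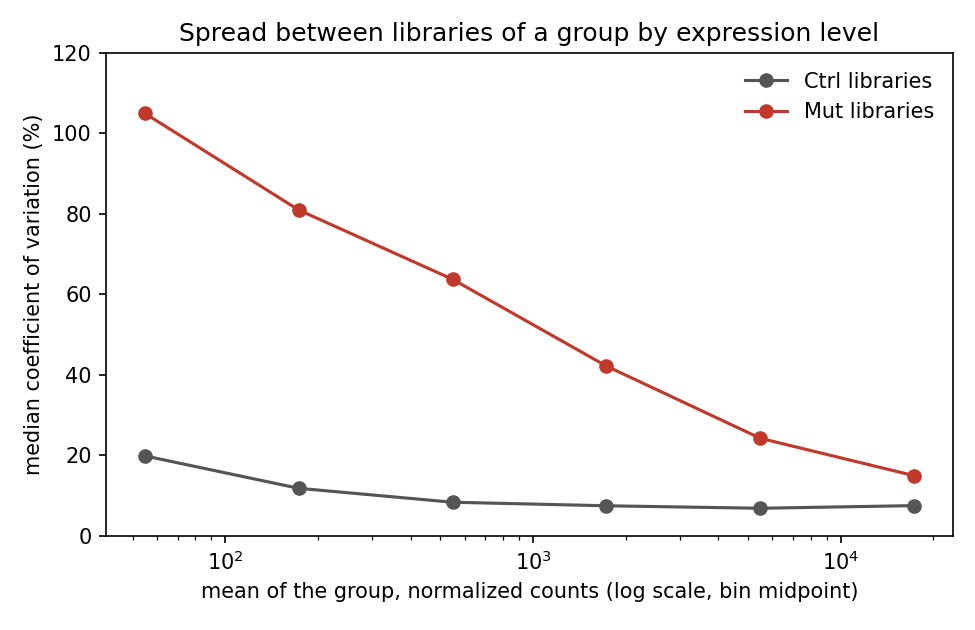
Median coefficient of variation (%) between libraries against group mean (normalized read count, log axis) for listed genes in Ctrl and Mut. From the lowest to the highest bin it goes from 19.8% to 7.47% in Ctrl and from 105% to 14.9% in Mut.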

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

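The tests of the scatter, of genes within genes, of the cell division lists and of the lists past camera were chosen after those results had been seen, and the tests of gene counts over other splits were chosen before. Single Ctrl libraries stood apart from the other 4 in 8 of 124 sets of 5 values (6.45%), where chance gives about 1 in 20. Of these 3 were in Ctrl 1, 3 in Ctrl 2 and 2 in Ctrl 5. In Ctrl 1, Stfa2 was at 92.2 against 24.9 to 37.3 in the others, and Spry2 at 187 against 224 to 238. In the same library mt-Atp6 was at 292 against 182 to 211. In Ctrl 2, Krt6a was at 7.03 against at most 1.02, Vwf at 544 against 397 to 412, and Oas2 at 1951 against 2350.4 to 2459. In Ctrl 5, Msmo1 was at 633 against 754 to 797, and Stmn2 at 866 against 974 to 999.9.

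The 8 libraries can be split into 3 and 5 in 56 ways. Only the real split, 1 of 56, called as many genes in limma (3458 in all, 1265 higher and 2193 lower), and the highest other split called 26, 0 and 26. Since the authors chose the listed genes on the real split, this says nothing about chance. Of the 56 splits, 6 called as many lists as the real one with camera (11, and 11 in the highest other). This too says nothing about chance, for the same reason, and because the 5 others had 0 or 2 Mut libraries in the group of 3 and so still part Mut from Ctrl in large measure. Splits with 1 Mut library in that group called 0 to 6 lists.

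The Mut libraries scattered more than the Ctrl libraries at the same level, with a median coefficient of variation of 42.2% in genes with a mean of 1000 to 3000. Fewer reads are argued against, since Ctrl reads thinned to the read scale of the Mut libraries gave 6.73%. Cultures that differ by 1 relative size in every gene are argued against by a slope of -0.90 ± 0.05 (SE, 846 genes) of log squared variation on log mean. These genes had all passed the authors' adjusted p limit on the same libraries, which can shape their scatter. A small number of RNA molecules entering the Mut libraries may have added part of this scatter: the variance per unit mean was alike at 3000 to 10000 and at 1000 to 3000 (ratio 0.935), although in genes higher in Mut it was 78.8 at 30 to 100, where 3 values cap it at 3 times the mean, and 693 at 10000 to 30000, and between 1000 and 3000 it stood at 432, 238 and 104 reads in Mut 1, 2 and 3. If that scale held at low levels, genes below a Ctrl level of 261 may miss Mut reads by sampling alone. Counts above 0 but far below 1 unit argue against a fixed unit there: Bub1 had 5 reads and Cdca7 4 over the 3 Mut libraries. The level of 261 is therefore a rough mark only, and other differences between Mut cultures stay open. Genes below it make up 1373 of the 2193 lower genes and all 532 without a Mut read. In simulated libraries with 1 unit size for every Mut library, limma called 35.6% of unchanged genes (33.3% as lower), against 0.479% without such loss. The estimated units differed, at 995, 209.5 and 175 normalized counts in Mut 1, 2 and 3. The simulation also left out the authors' selection, so it gives no rate of false calls for the listed genes.

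Genes that lie within another gene's span never had more reads than the outer gene, in 249 of 249 pairs of listed genes and all 8 libraries. Timp1 within Syn1 is an example. Counting over exons alone is argued against only if such neighbours change independently. The 23 pairs on opposite strands with no shared exon bases all held this order (binomial p = 2.12e-07, against 51.3% for random genes of the same level). The same comparison over all pairs with no shared exon bases (binomial p = 2.66e-10) cannot decide on neighbours that change together. An inner gene with a lower mean that changes with its outer gene keeps this order, which random genes need not do. Reads counted over whole gene spans may explain the order, which all 33 pairs with no shared exon bases held, so values of outer and overlapping genes may include reads of another gene, and no biological explanation was tested.

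The listed genes of the cell cycle, replication and histone lists were lower in Mut without exception, and their summed values were 13.4-fold, 5.50-fold and 5.40-fold lower. Loss of rare molecules by chance is argued against by an upper bound of 5.47e-29 on its probability, the largest over the 3 lists, or 7.21e-10 at 2 times the molecule scale, which was itself estimated from these libraries. A single wrong scaling factor cannot make the gap between the listed members of the cell cycle and glycolysis lists, in which it cancels. Their median log2 fold changes were -5.63 and 2.30 (SD between genes 1.475 and 1.125), a gap of 7.93. That gap is no test, because the glycolysis list was picked for it after the results had been seen. All listed genes also had an absolute log2 fold change above 1.5 in the authors' table, which alone sets such lists apart. Such a factor is not excluded for the absolute fall of the 3 lists. The ratios between their summed values, in which it also cancels, differed between Mut and Ctrl by -1.47 (cell cycle over histones, 95% interval -4.11 to 1.16), -1.45 (cell cycle over replication, -4.12 to 1.21) and -0.02 (replication over histones, -0.22 to 0.18) in log2. Exact permutation of the 8 libraries gave p = 0.0357, 0.0179 and 0.857, unadjusted, but such a p also counts the wider scatter of the Mut libraries. The Mut libraries differed: log2 cell cycle over replication was -0.26, -2.35 and -1.76 in Mut 1, 2 and 3, against -0.07 to 0.11 in Ctrl. For cell cycle over histones it was 1.12, -0.95 and -0.50, against 1.06 to 1.60 in Ctrl, so Mut 1 lay within the Ctrl range. Slower division of the cells that received MAP3K3 I441M stays open and was not tested, as does a difference in cell density or time in culture between the groups.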

How the results depend on the processing

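The edgeR, TMM, total, Ctrl subset, mean-of-200 and nested-member alternatives were chosen after the data were seen. Leaving out each library gave 3413 to 3497 changed genes, 1220 to 1304 higher and 2193 lower, and 9 to 12 lists. Other alternatives gave 1868 to 3574 changed genes and, with camera at the preset correlation, 9 to 13 lists. With a mean of at least 200 over all 8 libraries, 1868 genes changed, 1082 higher and 786 lower, by construction: such a mean keeps genes that are high in Mut and drops genes that are low there, so it gives no estimate of the share of lower genes. With Ctrl 3 and 4 alone, a smaller group, 2909 genes changed, 1062 higher and 1847 lower, and with Ctrl 1, 2 and 5 alone 3343, 1168 and 2175. Size factors from the listed genes shifted log2 fold changes by -1.49 (median of ratios), -0.80 (TMM) or -1.45 (total), leaving 775, 1125 or 817 genes higher. Genes with few Mut reads shifted less, through the added count of 1. Because these factors assume no change on balance among genes chosen as changed, lost and kept calls do not decide between scalings. The share of lower genes was 63.4%, and 73.9% and 72.9% with median of ratios and total. The MEKK3-KLF, interferon and mesenchymal transition lists passed in at least 1 alternative (smallest adjusted p = 0.0115, 0.0126 and 0.00350). An estimated correlation left 0 lists, and the cause was not tested. Fry, which compares no list with other genes, called 22, but all members had been chosen as changed, so this count is no independent evidence. Of 119 named genes, 107 kept direction and call in each of 21 alternatives that tested them, and 114 outside the 3 rescalings. With median of ratios and total, mt-Atp6 reversed to -0.058 and -0.011, through that shift, and Klf2, Tek, Plec, Cd68, Aif1, Map2k1, Map2k4 and Mapk14 lost their calls. With Ctrl 3 and 4 alone, Rpl3, mt-Atp6 and Aif1 lost theirs, as mt-Atp6 did with TMM and Aif1 with thinned reads or Ctrl 1, 2 and 5. Mmp13 and Krt8 passed with DESeq2, edgeR and limma-voom. DESeq2 and edgeR called all 3574 listed genes, which the authors had chosen on the same libraries, so those passes are no independent evidence. No paired analysis was possible because the numbers do not tie any Mut library to a Ctrl library. The planned Map3k3 value is missing from the table and was not analysed here. Genes with few Mut reads are measured with little precision. The folds of genes with 0 Mut reads are lower bounds for read counting only, not for loss of molecules.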

Other observations

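The name families and their level-matched draws were chosen after the values had been seen, while the gene lists were fixed earlier. Several signalling and stress groups held genes that moved apart. Of 31 MAP kinase cascade components, 4 were listed, 3 rose and 1 fell. The kinase genes Mapk14, Map2k1 and Map2k4 rose 3.34-fold, 2.95-fold and 3.04-fold, the first overlapping AC170998.1 and the second Uchl4. With the median-of-ratios or total factors from the listed genes, 0 of these 3 passed in limma. Of 25 PI3K-mTOR genes, 2 rose and 2 fell, among them Eif4ebp1, a repressor of translation initiation, up 4.74-fold to 5304 ± 573, and Deptor, an mTOR inhibitor, down 8.26-fold. With the median-of-ratios factors, 1 gene of that list passed as higher. Of 28 NRF2 and oxidative stress genes, 2 rose and 2 fell, with Srxn1, which restores peroxiredoxins, up 9.71-fold and the cystine transporter gene Slc7a11 down 4.21-fold (8.10-fold without Mut 3). Of 21 Wnt and beta-catenin genes, 2 rose and 4 fell (camera adjusted p = 0.932). Nkd2, an antagonist of Wnt signalling, rose 13.4-fold, Ccnd1, which overlaps LTO1, 3.91-fold, and the receptor gene Fzd4 fell 4.59-fold. Of 33 unfolded protein and integrated stress response genes, 4 rose and 3 fell (camera adjusted p = 0.636). Ppp1r15a, a phosphatase regulator that overlaps Tulp2, rose 5.33-fold, and Aldh18a1, of proline synthesis, fell 4.13-fold. With the median-of-ratios or total factors, 3 members of that list lay above 0 and 4 below, and 2 passed as higher, as with TMM.

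The cell type and housekeeping groups given next had 0 to 6 listed genes each. Of 24 endothelial-mesenchymal transition genes, 3 rose and 2 fell (camera adjusted p = 0.280), with Cd44, the hyaluronan receptor, up from 1899 ± 150.4 to 56275 ± 992 and Mmp2 at least 49.7-fold lower. With the median-of-ratios or total factors, 2 genes of that list passed as higher. Of 16 venous and lymphatic genes, 1 rose and 4 fell (camera adjusted p = 0.402), with Tll1, a metalloprotease gene, down 32.0-fold (54.2-fold without Mut 2). Of 18 pericyte and smooth muscle markers, 2 rose and 4 fell (camera adjusted p = 0.894). Anpep rose 37.0-fold from 62.4 ± 6.11, Mylk fell from 5654 ± 109.7 to 1808 ± 779, and Higd1b fell at least 14.1-fold. Of 16 fibroblast markers, 1 rose and 2 fell, with Pdgfra up 18.0-fold from 64.3 ± 8.19. Of 18 macrophage and microglia markers, 2 rose and 2 fell. Fcer1g and Spi1 fell at least 14.5-fold and 6.87-fold, with no Mut read, and Cd68 rose 3.06-fold from 711 ± 42.8. The other, Aif1 (log2 3.34 ± 1.19), no longer passed without Ctrl 5, Mut 1 or Mut 3 (log2 3.11, 1.92 and 3.17). With the median-of-ratios and total factors Cd68 was at 0.02 and 0.07 (log2), and 0 macrophage, 0 venous and 1 of the pericyte markers passed as higher. Of 25 cholesterol synthesis genes, 1 rose, the sterol oxidase gene Msmo1 (6.26-fold), and 2 fell. Of 40 cytosolic ribosomal protein genes 2 were listed, and both fell, Rpl15, which overlaps Nkiras1, 3.73-fold and Rpl3, which overlaps Syngr1, 3.13-fold. Without Mut 3 the log2 fold change of Rpl3 went from -1.89 to -1.24, and without Mut 2 Rpl15 was 6.43-fold lower. Of 15 mitochondrial genes 1 was listed, mt-Atp6, which overlaps mt-Atp8 and mt-Co3 and rose from 216 ± 44.3 to 617 ± 255, but was at -0.06 and -0.01 (log2) with the median-of-ratios and total factors. Of 12 nuclear long RNAs 0 were listed. Of the listed genes matched to the annotation, 3568 were protein-coding and 4 of other kinds, so this says nothing about change in long RNAs.

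Among 36 families of genes with shared names, 3 had a direction unlike the listed genes as a whole (Fisher's exact test, adjusted over the families). That test and the matched draws count the genes of a family as independent. All 44 listed genes with names starting in Hist fell (adjusted p = 1.65e-08), where genes matched for Ctrl level gave 35.2% higher (one-sided permutation p = 1.0e-04, the smallest the draws can give). This family leaves out histone genes with other names. It shares members with the histone list above, such as Hist1h1d, so it is no separate result. Of 78 zinc finger genes named Zfp, 9 were higher and 69 lower (adjusted p = 1.95e-06), 11.5% higher against 36.8% in matched genes (one-sided permutation p = 1.0e-04, the smallest the draws can give). The third was protocadherin gamma A, with 12 genes, all higher, but these nest within one another along 1 cluster with shared exon bases and had similar values. They hold largely the same reads, so they are 1 signal and no p-value is given.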
